A study of Homo sapiens with 5 samples.

How the data were processed

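Total RNA from 2 MCF-10A and 3 MDA-MB-231 samples was turned into labelled cDNA and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The deposited table holds 1 log2 signal per probe set and array, and RMA, a method of background correction, normalization between arrays and probe set summary, is named per the submitters' processing notes. The version of RMA, the probe set library, any filter and the genome build are not given in the sources used here. The log2 scale was read from the deposited values, which run from 2.72 to 14.9 with array medians between 7.80 and 7.92. Arrays had nearly but not exactly equal distributions, and for 41.9% of genes at least 2 arrays share the same value, which normalization between arrays can produce. Scanner files were not used here, so that background and normalization could not be redone from the probes.

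The table holds 32321 probe sets. The platform annotation gave 1 gene symbol for 19158 of them, several for 1388, which were left out, and none for 11775, which stayed unnamed. Of the single-symbol probe sets, 19128 were matched by gene number to RefSeq genes on the assembly GRCh38.p14, and 0 symbols changed. That assembly was used for names, chromosomes, gene lengths and the order of neighbouring genes, and no coordinates are given. For the 637 genes with more than 1 probe set, the one with the highest mean over all 5 arrays was kept, which left 18404 genes. Genes without a probe set of their own are not reported here.

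Samples were grouped by the cell line and replicate number in their titles. Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, two-sided), with the line as the sole factor, 3 residual degrees of freedom and 1.19 prior degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its absolute log2 difference was at least 1. The labels call the samples biological replicates of a line; p-values measure the spread between these samples, and do not extend to other lines. No filter on dim genes was applied. The background level was the 95th percentile of the mean signals of 340 olfactory receptor genes. Where the dimmer line lay below it, the fold is given as at least the brighter mean over that level.

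Gene lists and chromosomes with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 43 lists or the 24 chromosomes, and again with an estimated correlation. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names, from called genes whose arrays do not overlap between lines, the 12 with the largest difference in each direction, up to 4 called genes with the largest absolute difference in each list, and a set of genes of special interest whatever their values. Genes named only in the closing part on neighbouring genes were chosen after their values were seen.

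The gene test was tested on simulated data with the means and spread of this comparison, with 200 of 18404 genes changed. It called 88% of genes changed by 1.5 on the log2 scale, 98% of those changed by 2, 94% of those changed by 3 and 100% of those changed by 4, and 0 unchanged genes. Each rate rests on a part of the 200 changed genes. The minimum difference of 1 alone keeps most unchanged genes from a call, so the count of 0 says little about false calls. In the data 26.8% of genes had an adjusted p under 0.05, a larger share than was changed in the simulation. Of 200 unshifted lists, 2% had a camera p under 0.05, and a planted list of 40 shifted genes was found with the preset and with the estimated correlation. Genes were simulated as independent, so this does not show how often camera errs where the genes of a list vary together. In the data the estimated correlation was 0.528 for G2/M and mitosis genes and -0.0107 for epithelial junction and identity genes, against the preset 0.01.

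The alternatives were the mean of a gene's probe sets or each probe set on its own, a trended robust variance, array weights, centring on array medians, cyclic loess, a filter at the background level, other fold and p thresholds, limma's treat, leaving out each array, the replicate number as a block, and, for lists and chromosomes, an estimated correlation, limma's fry and camera on ranks. Added after the data were seen was the removal, among genes above background, of a trend of the differences with gene length, local gene density and signal level (natural splines, 4 degrees of freedom each, with the median of all genes kept), for the medians of lists and called chromosomes. Genes counted here as above background by their mean over all 5 arrays. Bootstrap intervals come from 10000 resamples of the genes of a list or chromosome, and not of arrays. They measure the spread among genes taken as independent, and not the uncertainty of the difference between the lines.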

Results

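Gene expression was measured in 2 human breast cell lines with whole-transcript microarrays, in a series about the attachment of DNA to the nuclear matrix, the protein scaffold that remains when soluble chromatin is removed from a nucleus. MCF-10A is a non-tumorigenic breast epithelial line, grown with epidermal growth factor, insulin, cholera toxin and hydrocortisone. MDA-MB-231 is a breast cancer line derived from a metastatic site, and its culture followed another protocol. There were 2 MCF-10A arrays and 3 MDA-MB-231 arrays, described as biological replicates. Each difference below is MDA-MB-231 minus MCF-10A on the log2 scale, so that 1 unit is a 2-fold change. Line and culture protocol changed together, and their parts in a difference cannot be separated here. Across the 18404 genes, arrays of the same line correlated with r between 0.991 and 0.993, and arrays of different lines with r between 0.897 and 0.908. The median SD of a gene between replicates was 0.0906 in MCF-10A and 0.115 in MDA-MB-231. The precision of every value is limited by the number of arrays.

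The first comparison asked which genes the lines express at different levels. The epithelial genes CD24, CDH1, KRT5 and KRT15 were bright in MCF-10A and lay below background in MDA-MB-231, while ANKRD1, EDIL3 and ENPP1 were bright in MDA-MB-231 and below background in MCF-10A. In all, 891 genes were higher and 1205 were lower in MDA-MB-231 (limma, Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold). All 2096 called genes had arrays that did not overlap between the lines, which chance gives for 20% of genes and which held for 50% of all genes tested. Olfactory receptor genes, which breast cells are not known to use, served as a gauge of background, and the 95th percentile of their mean signals was 7.50. Where the dimmer line lay below that level, folds are given as lower bounds against it. This level lay above the MCF-10A mean of 270 of the higher genes and above the MDA-MB-231 mean of 374 of the lower genes. The 46 called genes that lay below it in both lines have no fold. With these bounds, 9 of the higher and 55 of the lower genes changed by at least 16-fold. The log2 differences given below are those of the signals as measured, and the order among genes whose dimmer line lay below background is not measured.

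**Figure D1:**
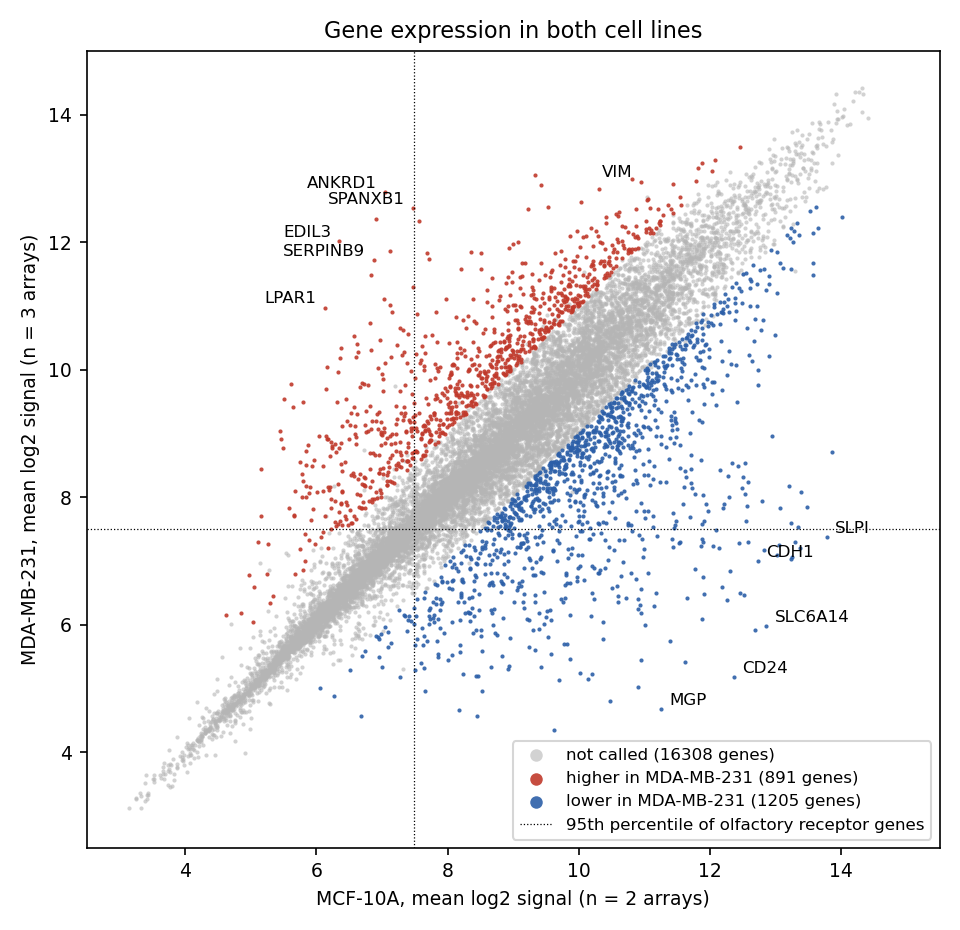
Mean log2 signal of each of 18404 genes in MCF-10A (x axis, 2 arrays) and MDA-MB-231 (y axis, 3 arrays). Red points are the 891 genes higher and blue points the 1205 genes lower in MDA-MB-231, grey points the genes not called, and dotted lines mark the background level of 7.50. CD24, at 12.37 in MCF-10A and 5.17 in MDA-MB-231, is among the genes farthest from the diagonal.

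Among the 12 lower genes taken for the size of their log2 difference was CD24, a glycosylated surface protein of epithelial cells, which stood at 12.37 ± 0.11 (SD, n = 2) in MCF-10A and 5.17 ± 0.46 (SD, n = 3) in MDA-MB-231. The difference was -7.19 ± 0.30 (SE, limma adjusted p = 0.00113), at least 29.2-fold over background. The secreted protease inhibitor SLPI differed by at least 77.8-fold over background (-6.40). The group also held the amino acid transporter SLC6A14 (-6.87), the serpin SERPINB5, known as maspin (-6.78), and the matrix protein MGP (-6.57). The basal keratins KRT15 and KRT5 differed by -6.20 and -6.16. The lipase family member PNLIPRP3 (-6.20), the retinoid-responsive gene RARRES1 (-6.19), the secreted glycoprotein AZGP1 (-6.05), the aminopeptidase ANPEP (lower by at least 55.8-fold) and the epithelial integrin subunit ITGB6 (-5.96) completed the group. All 12 lay below background in MDA-MB-231, and their adjusted p-values ran from 0.000128 to 0.00113.

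Among the 12 higher genes taken for the size of their log2 difference was ANKRD1, an ankyrin repeat protein induced through YAP, which rose from 7.04 ± 0.19 (SD, n = 2) to 12.78 ± 0.37 (SD, n = 3). Its difference was 5.74 ± 0.25 (SE, limma adjusted p = 0.00125), at least 39.1-fold over background. EDIL3, an extracellular integrin ligand, rose by 5.67, and the ectonucleotidase ENPP1 by 5.46. SPANXB1, a gene normally expressed in testis, rose by 5.06, and SPANX genes are near-identical copies, so its signal may belong to several of them. The lysophosphatidic acid receptor LPAR1 rose by 4.85, the granzyme inhibitor SERPINB9 by 4.84, the growth factor BMP4 by 4.78 and the mitochondrial carrier UCP2 by 4.74. The adhesion receptor ADGRF5 (4.65), the zinc finger gene ZNF737 (4.17), the microtubule-binding protein MAP1B (4.15) and the G protein subunit GNG11 (4.07) completed the group. ZNF737 was the least even of them between replicates, with an SD of 0.99 in MCF-10A. BMP4 and MAP1B lay above background in both lines, and the other 10 were below it in MCF-10A.

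Leaving out MCF-10A replicate 1 reduced the counts to 339 higher and 712 lower genes, and leaving out MCF-10A replicate 2 to 418 and 631, with the remaining MCF-10A array assumed to vary like the MDA-MB-231 arrays. Of the 155 called genes chosen for naming, none changed direction in any alternative run, which their choice for large differences makes likely. Among all 2096 called genes, 1 had the opposite sign with the mean of a gene's probe sets, 1 without MDA-MB-231 replicate 2 and 1 without replicate 3.

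The second comparison asked whether genes of known functions moved together, using 43 gene lists fixed before the data were examined. With limma's camera, which sets a list against all other genes at a preset correlation of 0.01, 18 lists differed, 7 toward higher and 11 toward lower levels in MDA-MB-231. With a correlation estimated from these arrays none of the 18 passed, and the lowest adjusted p was 0.0651. Counts of genes below are adjusted over all genes tested, and the count adjusted over the list alone is given where it differs.

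Genes of the epithelial state made the strongest group. Of 35 measured genes for epithelial junctions and identity, 28 were lower and 0 were higher, with a median difference of -2.38 (camera adjusted p = 1.43e-20, adjusted p = 0.0651 with an estimated correlation). CDH1, which encodes the adherens junction protein E-cadherin, differed by -5.72 ± 0.10 (SE, limma adjusted p = 0.000437), a decrease of at least 37.5-fold. RAB25, a small GTPase of epithelial trafficking, differed by -5.24, the membrane protein MAL2 by -5.16 and the tight junction gene CLDN1 by -4.85. Of 40 genes for desmosomes and the cornified envelope, 23 were lower (24 adjusted over the list alone) and 0 were higher, with a median of -1.71 (camera adjusted p = 4.28e-13, adjusted p = 0.468 with an estimated correlation). The kallikrein proteases KLK7 and KLK5 differed by -5.92 and -5.23, and the desmosomal cadherin DSG3 by -5.60. Markers of basal mammary epithelium were lower for 10 of 21 genes and higher for 1 (camera adjusted p = 3.08e-05, adjusted p = 0.468 with an estimated correlation), with the basal cadherin CDH3 at -5.27. Markers of luminal mammary epithelium were lower for 9 of 29 genes and higher for 1 (camera adjusted p = 0.000673, adjusted p = 0.468 with an estimated correlation). Among them the mucin MUC1 differed by -4.18, the secretory protein AGR2 by -2.53 and the receptor ERBB3 by -1.99. Lineage transcription factors were lower for 10 of 42 genes and higher for 1 (camera adjusted p = 0.000547, adjusted p = 0.468 with an estimated correlation). TFAP2A (-2.27), the Notch target HES1 (-1.92) and KLF5 (-1.80) fell, and RUNX2, a regulator of bone formation, rose.

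Of 44 mesenchymal genes, 6 were higher and 7 were lower, the median was 0.16, and the list was not called by camera (adjusted p = 0.23), while limma's fry, which asks whether a list's own genes move one way, called it higher (adjusted p = 0.00886). The receptor kinase AXL rose by 3.48 and the mesenchymal cadherin CDH11 by 3.34, while the fibroblast activation protein FAP differed by -4.04. Integrins (0 higher and 4 lower of 24), hemidesmosome genes (0 and 4 of 15) and keratins (1 and 8 of 48) were not called as lists by camera, with adjusted p-values of 0.778, 0.159 and 0.0622, and were called lower by fry (0.0024, 0.000805 and 0.0143). Integrins had a median of 0.02 and a mean of -0.52, and keratins a median of -0.05 and a mean of -0.65. Their fry calls therefore do not mean that most integrins or a typical keratin fell. The keratin list was called lower after centring on array medians (camera adjusted p = 0.0286), after cyclic loess (0.0204) and among genes above background (0.0178), and its adjusted p ran up to 0.203 when single arrays were left out. Its median above background went from -0.16 to -0.06 (95% bootstrap interval -0.70 to 0.18) after the removal of a trend with gene length, gene density and level. Lower members of these lists included the integrin subunits ITGB8 (-4.54), ITGB2 (-2.20) and ITGB4 (-1.39), the laminin chain LAMB3 (-1.67) and the keratins KRT10 (-5.65) and KRT23 (-4.24).

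Cell division genes stood higher in MDA-MB-231. Of 48 genes for G2/M and mitosis, 26 were higher and 0 were lower (1 lower adjusted over the list alone), with a median of 1.09 (camera adjusted p = 5.84e-15, adjusted p = 0.468 with an estimated correlation). The mitotic kinesins KIF14 and CENPE rose by 2.37 and 2.36, the spindle protein ASPM by 2.34 and the spindle regulator DLGAP5 by 2.21. Of 48 genes for G1/S and DNA replication, 11 were higher and 0 were lower (camera adjusted p = 9.49e-07, adjusted p = 0.468 with an estimated correlation), among them the polymerase subunit POLE2 (1.88), the checkpoint protein CLSPN (1.57) and thymidylate synthase TYMS (1.41). Targets of p53 moved the other way, with 19 of 38 lower and 1 higher and a median of -0.98 (camera adjusted p = 3.37e-08, adjusted p = 0.468 with an estimated correlation). The stress cytokine GDF15 differed by -4.33, the cyclin-dependent kinase inhibitor CDKN1A by -3.08 and CYFIP2 by -2.77. Of 30 genes induced through YAP and TEAD, 12 were higher and 1 was lower (camera adjusted p = 0.000697, adjusted p = 0.468 with an estimated correlation). The matricellular gene CCN1 rose by 3.31 beside ANKRD1 and AXL, and IGFBP3, which binds insulin-like growth factors, differed by -2.12.

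Several metabolic lists were lower. Cholesterol synthesis genes were lower for 10 of 20 members (12 adjusted over the list alone) and higher for 0, with a median of -1.12 (camera adjusted p = 2.86e-07, adjusted p = 0.468 with an estimated correlation). The epoxidase SQLE differed by -2.51, the transcription factor SREBF2 by -2.01 and HMGCS1, an early enzyme of the pathway, by -1.99. Of 80 genes of the mitochondrial respiratory chain, 12 were lower and 0 were higher, with a median of -0.48 (camera adjusted p = 1.56e-08, adjusted p = 0.468 with an estimated correlation). ATP5F1D differed by -1.69 and NDUFB9 by -1.59, and COX7A1, below background in MDA-MB-231, by at least 2.38-fold. Ribosomal protein genes shifted less, with a median of -0.27 over 66 genes, of which 6 were lower and 2 higher (camera adjusted p = 8.86e-05, adjusted p = 0.468 with an estimated correlation). For the 64 ribosomal genes above background the median was -0.28, and -0.26 once a trend of the differences with gene length, gene density and signal level was removed, a step added after the data were seen. Genes for glutathione, NRF2 response and aldo-keto reductases were lower for 14 of 35 members and higher for 4 (camera adjusted p = 0.00192, adjusted p = 0.468 with an estimated correlation). AKR1C2 and AKR1C1 differed by -5.63 and -5.16 and the transporter ABCC2 by -3.60, while GSTM3 rose by 3.69. AKR1C and GSTM genes have close paralogs that probes can share. Glycolysis and hypoxia genes, with 8 of 38 lower and 2 higher, were called narrowly (camera adjusted p = 0.0491, adjusted p = 0.468 with an estimated correlation), and the call was lost in several alternatives.

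Because the series concerns the nuclear matrix, proteins of the matrix, lamina and chromatin loops were followed as a list of their own. Of 51 measured genes 10 were higher and 1 was lower, with a median of 0.31 (camera adjusted p = 0.00192, adjusted p = 0.476 with an estimated correlation). The cohesin subunit SMC3 rose by 1.67, topoisomerase TOP2A by 1.62 and the lamina-associated protein TMPO by 1.60. TOP2A and TMPO are also known to rise in dividing cells. SATB1, which anchors chromatin loops to the matrix, was the lower gene, at -1.51 ± 0.08 (SE, limma adjusted p = 0.00188). The lamin genes did not reach a 2-fold difference. LMNA differed by 0.26 ± 0.09 (SE, adjusted p = 0.117) and LMNB1 by 0.65 ± 0.07 (SE, adjusted p = 0.00749). Genes for DNA methylation and Polycomb proteins were higher for 7 of 42 members and lower for 0 (camera adjusted p = 0.0328, adjusted p = 0.468 with an estimated correlation), with the methyltransferase EZH2 at 2.22 and its partner SUZ12 at 1.39, and this call was also lost in several alternatives.

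**Figure D2:**
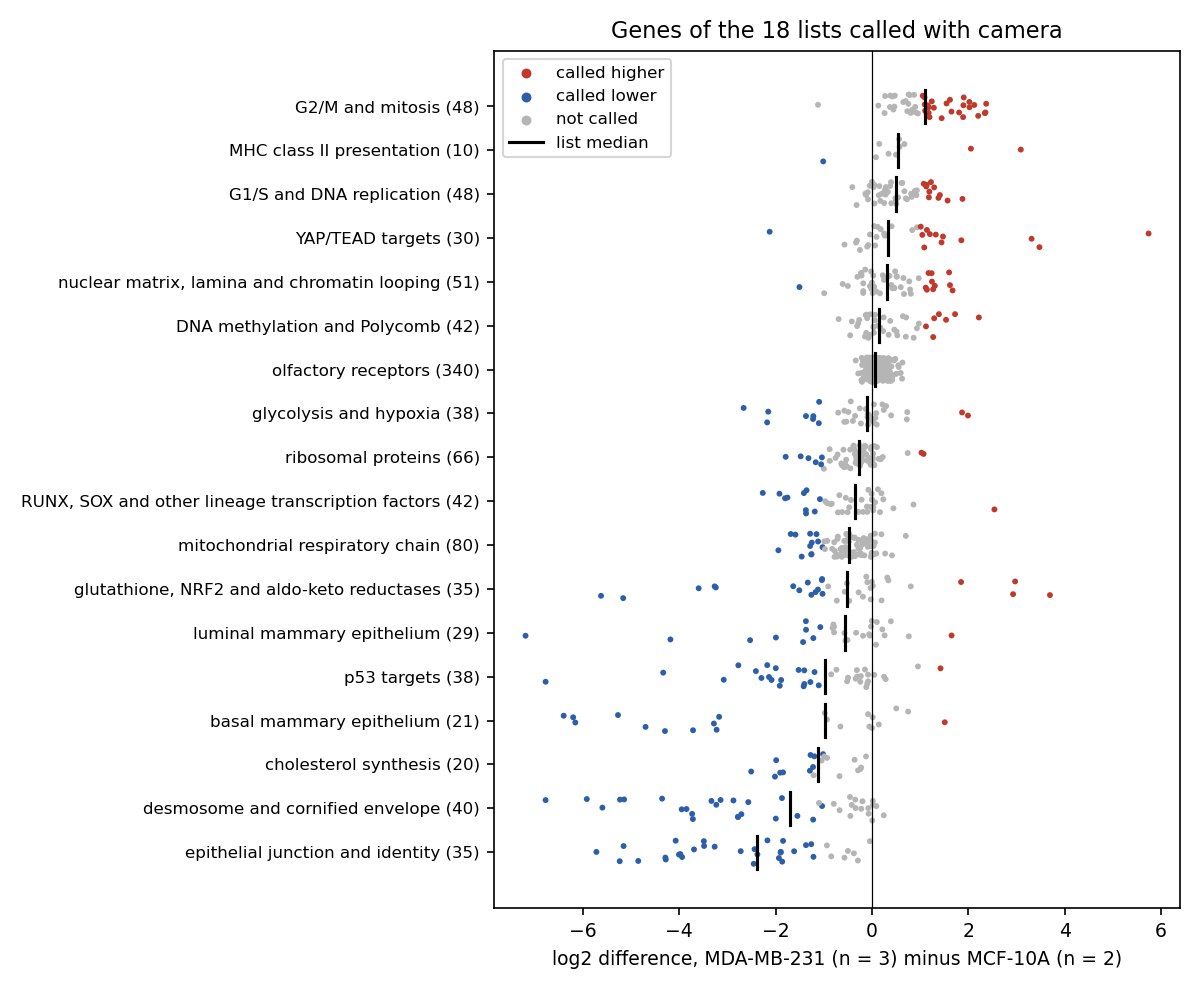
Log2 difference of every measured gene (x axis, MDA-MB-231 minus MCF-10A) in the 18 lists that camera called with a preset correlation, with the number of measured genes after each name. Points are genes, red when called higher and blue when called lower, and black bars are list medians, which run from -2.38 for epithelial junction genes to 1.09 for G2/M and mitosis genes.

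Among signalling and immune genes, few lists moved as a whole. The MHC class II list was called toward higher levels (camera adjusted p = 0.0265, adjusted p = 0.476 with an estimated correlation), although 2 of its 10 genes were higher and 1 was lower, and the call did not hold in every alternative. HLA-DPA1 and HLA-DPB1 rose by 3.09 and 2.05, and HLA-DOB differed by -1.01. The type I interferon list held 12 higher and 5 lower genes of 39 and was not called (camera adjusted p = 0.1), but was called higher after centring on array medians (0.0284) and after cyclic loess (0.0325), with up to 0.315 when single arrays were left out. IFIT1 and IFIT3, which act against viral RNA, rose by 3.09 and 2.57, whereas OAS1 and TRIM22 differed by -3.92 and -3.37. Of 40 genes for NF-kB and inflammatory cytokines, 8 were higher and 4 lower (camera adjusted p = 0.841), with the cytokine IL6 at 2.72, the immune checkpoint ligand CD274 at 2.72 and IL18 at -3.04. For EGF family ligands (camera adjusted p = 0.841), EPGN differed by -5.66 and NRG1 by 3.37, 1 gene in each direction of 10. MAPK output genes were split between 5 higher and 4 lower of 28 (camera adjusted p = 0.433), with ETV1 at 2.92, FOSL1 at 1.68, FOS at -1.99 and JUNB at -2.02. TGF-beta targets were higher for 3 and lower for 6 of 30 (8 lower adjusted over the list alone; camera adjusted p = 0.0973), with TGFBR1 at 1.64 and ID2 at -3.36. In the Wnt list 2 genes were higher and 2 lower of 51 (camera adjusted p = 0.359), with LEF1 at 1.84 and the Wnt antagonist SFRP1 at -3.62. Of 41 matrix protease and plasminogen genes 3 were higher and 7 lower (camera adjusted p = 0.359), with the plasminogen activator PLAT at 2.64 and MMP7 at -3.45. A list of metastasis genes known from bone and lung sublines of MDA-MB-231 held 5 higher and 6 lower genes of 26 (7 lower adjusted over the list alone; camera adjusted p = 0.841). The MHC class I list held 3 higher and 0 lower genes of 13 (camera adjusted p = 0.433), with the peptidase ERAP1 at 1.82. The unfolded protein response list held 3 lower genes of 34 (camera adjusted p = 0.064), with the serine synthesis enzyme PHGDH at -3.33. Of these lists without a camera call, fry called TGF-beta targets (adjusted p = 0.00602), EGF family ligands (0.01) and matrix protease and plasminogen genes (0.01) lower. The EGF ligands had a median of 0.10 and a mean of -0.17, so their fry call does not mean that most of them fell.

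Markers of cell types that the cultures should not hold were not called by camera. Fry called leukocyte markers (adjusted p = 0.00886) and fibroblast collagen markers (0.0248) lower and did not call endothelial and adipocyte markers (0.114). A comparison of lines does not show whether such markers are absent. Above background were 6 of 15 leukocyte markers in each line. Of 13 endothelial and adipocyte markers, 5 were above it in MCF-10A and 3 in MDA-MB-231. Leukocyte markers were higher for 1 and lower for 2 of 15 genes (camera adjusted p = 0.359), with LAPTM5 at 2.53, CORO1A at -1.84 and CD14 at -4.17. Their median was -0.08 and their mean -0.26. Fibroblast collagen markers, all 10 of which also stand in the mesenchymal list, had 2 lower genes, FAP and DCN (camera adjusted p = 0.891). Their median was 0.13 and their mean -0.73, so the fry call does not mean that most of them fell. Endothelial and adipocyte markers were higher for 1 and lower for 3 of 13 (camera adjusted p = 0.841), with PECAM1 at -3.46.

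The genes fixed in advance as of special interest spanned the range of the data. VIM, the mesenchymal intermediate filament vimentin, rose by 2.00 ± 0.11 (SE, limma adjusted p = 0.00181). RUNX2 rose by 2.54 ± 0.24 (SE, adjusted p = 0.0054), and the related RUNX1 differed by -0.19 ± 0.06 (SE, adjusted p = 0.0858), which did not pass. The proliferation marker MKI67 rose by 1.65 ± 0.18 (SE, adjusted p = 0.00746), and MYC fell by 1.05 on the log2 scale (SE 0.08, adjusted p = 0.00373). ESR1, the estrogen receptor, stood at 7.85 in MCF-10A and 7.04 in MDA-MB-231, close to the background level, and its difference of -0.80 did not reach 2-fold. CD44, a surface receptor often read beside CD24, was bright in both lines at 12.93 and 13.26. The growth factor receptor EGFR differed by 0.50 ± 0.13 (SE, adjusted p = 0.0587). CDKN2A lay below background in both lines, with a difference of -0.02.

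**Figure D3:**
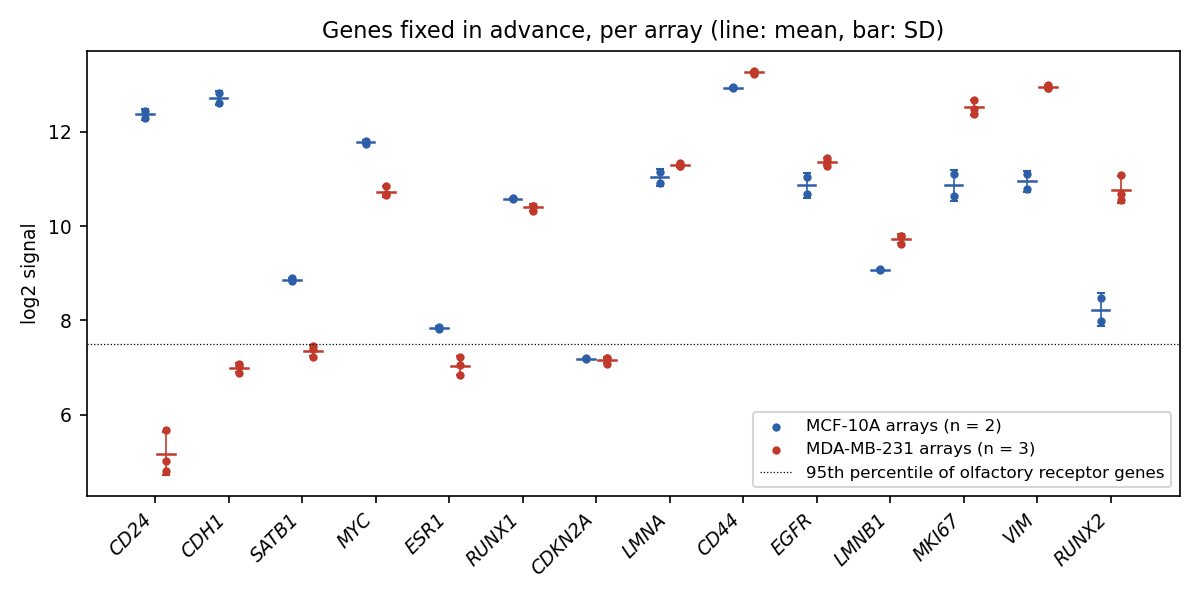
Log2 signal (y axis) of the genes fixed in advance on each MCF-10A array (blue, n = 2) and each MDA-MB-231 array (red, n = 3), with horizontal lines for means, bars for SD and a dotted line at the background level of 7.50. CD24 and CDH1 show the widest gaps downward, and VIM and RUNX2 the widest upward, at 2.00 and 2.54.

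Further lists covered gene families and gene clusters. None of 340 olfactory receptor genes was called by limma, yet the list as a whole was called higher by a median of 0.06 (camera adjusted p = 0.0488, adjusted p = 0.83 with an estimated correlation), and this call was lost in several alternatives. Of 439 zinc finger genes 42 were higher and 6 lower (camera adjusted p = 0.065), and the list was called higher after centring on array medians (0.0284), after cyclic loess (0.0258) and without MCF-10A replicate 2 (0.0205) or MDA-MB-231 replicate 1 (0.0212), but reached 0.313 without MCF-10A replicate 1, with ZNF486 at 3.83, ZNF43 at 3.77 and ZNF93 at 3.64. Histone cluster genes were lower for 14 and higher for 3 of 57 (camera adjusted p = 0.359), with H2BC7 at -5.87, H4C5 at -4.68, H1-5 at -4.16 and H1-1 at -3.99. Zinc finger and histone genes are rich in close paralogs, so probes can read more than 1 gene. Taste receptor and defensin genes were higher for 4 and lower for 1 of 54 (0 higher adjusted over the list alone; camera adjusted p = 0.0859). Protocadherin cluster genes were higher for 1 and lower for 3 of 29 (camera adjusted p = 0.841), HOX genes lower for 3 of 27 (camera adjusted p = 0.182) and keratin-associated protein genes neither for any of 68 (camera adjusted p = 0.359). SPANXB1 was the sole called gene among 21 cancer-testis antigens (camera adjusted p = 0.0927), and KLHL9, at -2.90, the sole one among 8 genes of the 9p21 region (camera adjusted p = 0.0893). Fry called histone cluster (adjusted p = 0.00482), HOX (0.01) and 9p21 genes (0.0168) lower. It called zinc finger genes (0.0422) and cancer-testis antigens (0.0222) higher, and did not call olfactory receptors (0.391). Histone cluster and HOX genes had medians of -0.01 each and means of -0.50 and -0.23, so their fry calls do not mean that a typical member fell. Zinc finger genes and cancer-testis antigens had medians of 0.07 each and means of 0.23 and 0.35.

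The third comparison asked whether whole chromosomes differed between the lines. Genes of chromosome 16 stood lower in MDA-MB-231, with 114 lower and 7 higher of 759 genes and a median of -0.20 (camera adjusted p = 3.96e-08 over 24 chromosomes). Chromosome 22 had 30 lower and 2 higher of 423 genes and a median of -0.05 (camera adjusted p = 0.0208). On chromosome 8 there were 89 lower and 25 higher of 639 genes, with a median of -0.05 (camera adjusted p = 0.0314). With an estimated correlation the adjusted p-values were 0.407 for chromosome 16, 0.744 for chromosome 22 and 0.407 for chromosome 8. Among genes above background, removing the trend with gene length, gene density and level moved the median from -0.29 to -0.24 for chromosome 16, from -0.11 to -0.12 for chromosome 22 and from -0.17 to -0.27 for chromosome 8. Without MCF-10A replicate 1 chromosome 16 alone was called, and without MCF-10A replicate 2 chromosome 8 was lost.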

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

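The alternatives were planned before the data were examined, except the removal of a trend with gene length, gene density and level. Over all 2096 called genes, 1 had the opposite sign with the mean of a gene's probe sets, 1 without MDA-MB-231 replicate 2 and 1 without replicate 3. The 155 called genes chosen for naming kept their direction in every alternative run, and 101 of them were called in every refit that included them. Without MCF-10A replicate 1, 42 of these genes lost their call, and without MCF-10A replicate 2, 43 did. Over the arrays left out in turn, the counts ran from 339 to 774 for higher and from 631 to 1197 for lower genes, with the lowest values where 1 MCF-10A array was left and assumed to vary like the MDA-MB-231 arrays. The share of called genes that were higher was 42.5%, and 32.3% without MCF-10A replicate 1. With no minimum fold 2174 genes were higher and 2750 lower. With a minimum fold of 4 there were 208 and 407, with treat against a fold of 2 there were 193 and 424, and at an adjusted p under 0.01 there were 561 and 898. These follow from the stricter or looser thresholds themselves. The other normalizations, probe set rules, variance models, array weights and the background filter gave 837 to 917 higher and 1068 to 1358 lower genes. The lines' replicate numbers 1 and 2 are shared. Same-numbered arrays deviated together with r of 0.35 and 0.185 across genes, but 2 pairs do not establish pairing. Replicate 3 occurs in MDA-MB-231 alone, so a replicate block takes up that array. The line difference then rests on replicates 1 and 2 of each line. With the replicate block 743 genes were higher and 1117 lower, chromosome 22 (camera adjusted p = 0.0764, and 0.00367 to 0.103 over all refits) and the DNA methylation and Polycomb list (0.0859, and 0.0076 to 0.117) were not called, and 3 lists were added, the unfolded protein response (0.00366, and up to 0.172), keratin-associated proteins (0.0062, and up to 0.968) and taste receptors and defensins (0.00347, and up to 0.266). Leaving out MDA-MB-231 replicate 3 without a block added the same 3 lists. Of the 18 lists called, 14 were called in every fit run at the preset correlation and on ranks. The exceptions, each lost in at least 1 of these, were MHC class II, DNA methylation and Polycomb, glycolysis and hypoxia, and olfactory receptors. Lists were also gained. Median centring and cyclic loess added interferon, zinc finger and keratin genes, the background filter keratins, and leaving out single arrays at times cancer-testis, HOX, 9p21, zinc finger, keratin, unfolded protein response, keratin-associated protein or taste receptor genes. After trend removal the medians of the called lists kept their sign, with a 95% bootstrap interval that held 0 for glycolysis and hypoxia (-0.46 to 0.02). The median of the nuclear matrix, lamina and chromatin loop list fell from 0.34 to 0.23. Camera with an estimated correlation called 0 lists and 0 chromosomes, and fry, which asks whether a list's own genes move one way, called 31 lists and 9 chromosomes. The cause of the gap to the preset correlation was not tested. A higher correlation is not the cause for every set that lost its call. The estimates for epithelial junction genes (-0.0107) and chromosome 8 (0.00738) lay below the preset 0.01. Chromosomes called numbered 5 among genes above background, where chromosomes 4 and X were added, and from 1 to 3 over the arrays left out in turn; chromosome 16 was among them each time. Differences of genes near background are compressed on arrays, which limits what dim genes can show.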

Other observations

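The tests in this part, apart from the planned test of whole chromosomes, were chosen after the results were seen. Some runs of neighbouring genes differed in the same direction. The 12669 genes above background with an annotated length were cut into 316 blocks of about 40 consecutive genes on the assembly GRCh38.p14. A block on chromosome 10 from MCM10 to ACBD5 held 14 higher and 2 lower genes with a median difference of 0.65. On chromosome 14, a block from ARF6 to EXOC5 held 10 higher and 1 lower gene with a median of 0.60, and on chromosome 11 a block from EED to DCUN1D5 held 8 higher and 1 lower with a median of 0.65. In the other direction, the block from STMN4 to ADGRA2 on chromosome 8 held 12 lower and 1 higher gene with a median of -0.48, and its neighbour from BRF2 to CEBPD held 9 lower and 1 higher with a median of -0.54. Chromosome 8 was also called lower as a whole (camera adjusted p = 0.0314, 0.407 with an estimated correlation, and 0.00533 to 0.1 over the refits at the preset correlation), a call lost when either MCF-10A array was left out (0.1 and 0.0844). A block on chromosome 18 from PIK3C3 to ATP8B1-AS1 held 9 lower and 1 higher with a median of -0.44. These blocks were picked for the highest and lowest medians outside chromosome 16, whose own blocks reach -0.47 and are taken up below, and they were not tested.

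The zinc finger genes that rose lay mostly on chromosome 19. There 33 of 221 were higher and 1 lower, against 9 higher and 5 lower of 218 on other chromosomes. Other genes of chromosome 19 were higher for 17 and lower for 73 of 1087. A run of 35 consecutive measured genes from ZNF506 to ZNF254 held 32 genes with zinc finger names, 31 of them in the list just counted. All had a positive difference, and 16 were called higher, 15 of them in that list, and 0 lower. The run was noticed while several gene families were looked through, and the others are not reported here, so no p-value is given for its rise. There ZNF90 rose by at least 5.40-fold over background and ZNF826P by at least 3.79-fold. By contrast ZNF431 differed by 0.07 and ZNF91 by 0.23.

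A trend with gene length, local gene density and signal level carries 2.74% of the variance over all genes above background. That share does not bound its part in a small set. Removing the trend left the median of 22 zinc finger genes of the run at 1.085 (95% bootstrap interval over genes 0.76 to 1.71). Before, that median was 1.18, so the fitted trend is not the whole of the run's rise. These 22 lay above background in their mean over all 5 arrays, and 16 did so in both lines. The others lay below it in MCF-10A and passed through MDA-MB-231, so this filter favours genes that rose. Over all 32 the median was 0.98. An equal gain of every gene, as extra copies would give, was judged on the 16 zinc finger members above background in both lines. The run's other genes, near or below background, were left out. RPSA2 differed by 0.01 ± 0.14 (SE), GOLGA2P9 by 0.21 and CCNYL6 by -0.11. Differences of the 16 ran from 0.07 to 1.63, with an SD of 0.4964. That SD was 2.55 times their median standard error, short of the ratio of 3 set first. The differences repeated between replicates 1 and replicates 2 (Pearson r = 0.81 across members), so the measured changes were not all equal. But 91.2% of 729 other runs of 16 such genes repeated at least as well, and 70.6% had an SD at least as large. An equal gain with such ordinary spread added cannot be told apart from separate increases. Cross-hybridisation among paralogs cannot be told apart from separate increases either, because probe sequences were not used. Of the 16 members above background in both lines 3 differed by under 0.3, too few to decide. A shared change in the regulation of this cluster was not tested.

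Genes of chromosome 16 were lower along its length. Above background 618 genes had a median of -0.29, and 75.7% of them were lower. Each of 15 blocks had a median below 0, against 41.2% of blocks on other chromosomes. This was not particular to chromosome 16. On chromosome 22 every block also had a median below 0, from -0.22 to -0.05, and stayed below 0 after trend removal. A few strong genes do not account for the shift of chromosome 16, since its genes not called had a median of -0.1893. Removing the trend with length, density and level left a median of -0.2434 (95% bootstrap interval over genes -0.32 to -0.17), so the trend may carry a small part of the shift and not all of it. After the same step, which keeps the median of all genes at 0.004, chromosome 22 went from -0.11 to -0.12 (-0.16 to -0.07), chromosome 8 from -0.17 to -0.27 (-0.36 to -0.16), and the gene-dense chromosomes 17 and 19 had medians of 0.06 each. An equal loss along the whole chromosome cannot be told apart from partial or regulatory changes, since DNA copy number was not measured here. This explanation was first judged on the blocks before trend removal, all 15 of which lay below 0, with medians from -0.47 to -0.09. The count after trend removal, 14 of 15 below 0, was taken up later as the stricter one. Medians then stood at -0.005, -0.014 and 0.07 for the blocks from WASIR2 to CLDN9, and at -0.56 from ALG1 to COQ7. Neither count tests whether a loss is equal, since an uneven loss can also leave every block below 0.

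Mitosis genes had a median length of 28.4 kilobases and respiratory chain genes one of 9.24, against 26.3 for all genes above background, which raised the question of a length effect behind their opposite shifts. The difference between lines rose by 0.10 per 10-fold of gene length, and single arrays deviated from their line's mean with slopes from -0.061 to 0.035, so a length trend of technical origin may be present. The fitted trend carries 2.74% of the variance over all genes above background, which does not bound its part in a small list. Its removal moved the median from 1.09 to 0.9709 for mitosis genes (95% bootstrap interval over genes 0.78 to 1.11). For respiratory chain genes the median moved from -0.48 to -0.5019 (-0.66 to -0.35). The fitted trend is thus not the whole of either shift. Technical effects that do not follow length, density or level were not tested. Ribosomal protein genes, with a median length of 5.2 kilobases, went from -0.28 to -0.26 (-0.35 to -0.18). The authors' normalization between arrays was not redone and stays open. Growth rate and culture density, which the design ties to the line, were not tested.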
